A study of Mus musculus with 12 samples.

How the data were processed

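Gene expression was measured in fully grown germinal vesicle oocytes, which are arrested in prophase of the first meiotic division, of 4 genotypes. The control carried intact Ring1 and a floxed Rnf2 gene without Cre. The Ring1 mutant was homozygous for a Ring1 null allele with the same floxed Rnf2. The Rnf2 mutant carried floxed Rnf2 with a Cre transgene driven by the Zp3 promoter, which is active in growing oocytes. The double mutant combined the Ring1 null alleles with the floxed Rnf2 and Cre. Per the labels' protocols, each RNA sample came from 50 oocytes pooled from several hormone-primed females of a mixed genetic background, and the RNA was turned into cDNA by whole-transcriptome amplification before hybridisation to a whole-transcript array. There were 3 samples per genotype, called biological replicates in the labels. Whether pools of one genotype shared females is not given in the sources used here, so the p-values measure the spread between these pools. Every array was assigned to its genotype from the labels.

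The deposited table gave 1 log2 intensity per probe set and array, already normalized between arrays as far as the values show. The submitters' processing notes name R 2.10.0 and the affy package. The background correction and summarization method are not given in the sources used here. Array medians lay between 3.81 and 3.93 log2, and all 12 arrays were used. No 2 arrays held identical values. The deposited values come with no detection calls, so the 1040 olfactory receptor genes, taken to be mostly silent in oocytes, served as a reference for the floor. Their median was 2.58 and their 95th percentile 3.82 log2, and 12371 of 21093 genes had a mean above that percentile. A change of a gene near this floor is compressed, and the number of arrays limits the precision of every value.

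Of 34760 probe sets, 22807 named 1 gene in the authors' annotation, 1712 named several, 10210 named none and 31 were not listed there. Only the first kind was tested by gene. Symbols were brought up to date through a gene table of the GRCm38.p6 assembly. There, 19555 probe sets matched by gene number, 185 by accession, 877 by symbol and 564 by an older symbol, while 1626 kept the name in the annotation. The genome build of the array is not given in the sources used here, so that table was used for names, chromosomes and neighbourhood, and no coordinates are printed. For the 1004 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. This left 21093 genes.

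One linear model with a mean per genotype was fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p below 0.05. The 7 comparisons were each mutant against control, the double mutant against each single mutant, the Rnf2 mutant against the Ring1 mutant, and the Ring1 by Rnf2 interaction. The interaction is the Rnf2-loss effect in Ring1-null oocytes minus the Rnf2-loss effect in oocytes with Ring1. Errors given with log2 changes are standard errors of this fit, with n = 3 arrays per group.

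Gene lists were fixed before the data were examined. There were 21 lists of pathways, complexes and cell type markers, and 2 lists of genes within 10 Mb of Ring1 or of Rnf2. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The alternatives were camera with an estimated correlation, and fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. Named genes followed a rule fixed at the same time. They are Ring1 and Rnf2, the 10 largest rises and 10 largest falls among called genes with the 3 arrays of one group all on one side of the other's (5 each for the interaction, without that condition), and per list up to 4 called members with the smallest adjusted p, or the 2 members with the highest mean where none was called. A gene named outside this rule is said to have been chosen after its values were seen. A few genes that the rule names are not reported here.

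The fit was tested on simulated data with 21093 genes drawn from the observed spreads and 50 genes changed at each of several sizes in the double mutant. Against control, it recovered 20% of genes changed by 0.3 log2, 68% at 0.5, 94% at 1 and 100% at 2. Of 146 genes called there, 5 were unchanged. Far fewer genes were changed there than the 6690 called in the real comparison, and the spreads were assigned to genes at random. The cut-off of the adjusted p depends on the share of changed genes, so these rates do not carry over to that comparison. Alternatives covered the choice of probe sets, a filter on dim genes, other scalings, variance models, array weights, a fold threshold, the replicate number as a block, genes near the targeted loci, and leaving out each array in turn. Added after the data were seen were centring of each array on its most abundant 25% of genes and the mean of Cyp11a1 and Star as a covariate. Overlaps of calls between comparisons that share control arrays were left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.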

Results

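The series profiled germinal vesicle oocytes lacking one or both of Ring1 and Rnf2, the 2 E3 ligases at the core of Polycomb repressive complex 1, which ubiquitinates histone H2A at repressed genes. The question stated by the series title was what Polycomb does during oogenesis. Each of the 4 genotypes was measured on 3 arrays. Values within a genotype correlated between 0.996 and 0.997 across genes, and those of double-mutant arrays with the other genotypes between 0.977 and 0.982. The first principal component held 65.7% of the variance. It placed the 3 double-mutant arrays at 46.1 to 49.6 and the 9 others between -17.9 and -13.4. The second component held 6.7% and set the Ring1 mutants, at -16.1 to -12.1, apart from the controls and the Rnf2 mutants.

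**Figure D1:**
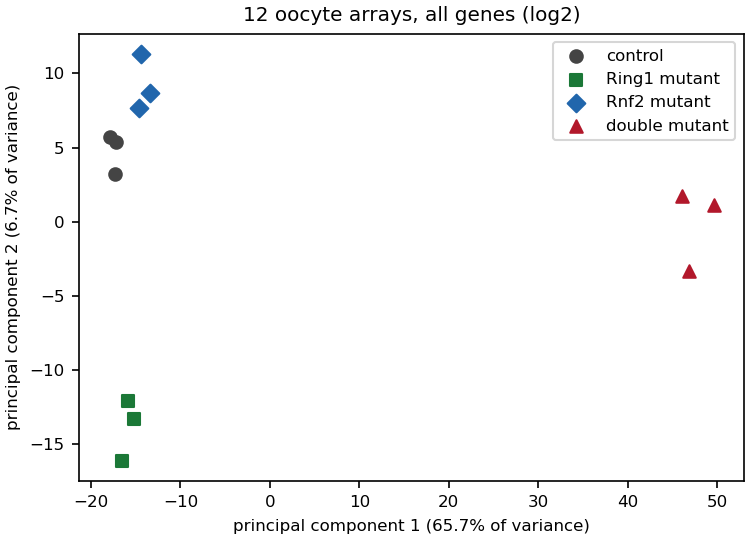
Principal components of the 12 arrays over all genes (log2 intensity), each point an array, with the share of variance on each axis. The 3 double-mutant arrays lie at 46.1 to 49.6 on the first component, away from the 9 others.

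Rnf2 transcript was lower in every array of the genotypes with Cre. It read 8.33, 8.44 and 8.23 log2 in the controls and 8.43, 8.53 and 8.43 in the Ring1 mutants. The Rnf2 mutants read 5.60, 5.93 and 6.04 and the double mutants 5.90, 5.68 and 6.01. Rnf2 fell by 2.48 ± 0.11 log2 in the Rnf2 mutant against control (limma, adjusted p = 5.6e-07) and by 2.47 ± 0.11 in the double mutant (limma, adjusted p = 1.0e-08). The position of its probes relative to the floxed exons was not used here. Ring1 read between 3.51 and 3.99 log2 on all 12 arrays, close to the 95th percentile of olfactory receptor genes (3.82), and differed from control by -0.05 ± 0.11 in the Ring1 mutant (limma, adjusted p = 0.92). This signal did not separate the genotypes, and the position of the probes relative to the deleted part was not used here, so it gives no check of the Ring1 genotype.

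The comparison of the double mutant with control asks what the oocyte transcriptome looks like without either ligase. The largest rises included Ddah1, an enzyme that degrades methylated arginines, by 4.64 ± 0.08 log2, the signalling molecule Bmp2 by 4.25 ± 0.09, the collagen-modifying enzyme Plod2 by 4.54 ± 0.11, and the germline RNA-binding protein Rbm46 by 4.23 ± 0.09. Amigo2 (4.54 ± 0.13), Gabarapl1 (4.49 ± 0.14) and the X-linked genes Tbl1x (4.54 ± 0.14) and Xlr (4.34 ± 0.13) rose as far. Mt1, a metallothionein, rose by 4.72 ± 0.17 but was as high in the Rnf2 mutant. The deepest falls were in Gsto2 (-4.69 ± 0.23), the hyaluronidase gene Spam1 (-2.55 ± 0.12), Uggt2 (-2.48 ± 0.25), Pot1b (-1.94 ± 0.13) and the voltage-gated proton channel Hvcn1 (-1.93 ± 0.08). Each of these had a limma adjusted p of at most 9.8e-06. Gsto2 and Uggt2 were also low in the Ring1 mutant. Of the 3 probe sets of Rpl27a, the one used fell by 2.71 while the others read 1.08 and -1.14, so its direction is uncertain.

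Altogether 6690 of 21093 genes were called in the double mutant against control by limma, 3004 higher and 3686 lower. Changes of at least 2-fold went mostly upward, in 636 of 802 genes. Of those 636 genes, 209 (32.9%) had a control mean below the 95th percentile of olfactory receptor genes. Among all genes the share was larger, 42.0% (8851 genes), so rises did not start near the floor more often than other genes. In the double mutant 202 of the 209 stood above that percentile. A 2-fold rise gives this by construction only for genes that started within 2-fold of it, and how many did was not counted. The balance of all calls depends on the scaling: with each array centred on its most abundant 25% of genes, a choice made after the data were seen, 4288 genes were higher and 2408 lower, after quantile normalization 3331 and 3299, and with each array centred on its median 2619 were higher and 4357 lower. The median change was -0.394 log2 over the called falls and 0.533 over the called rises, against -0.113 over those abundant genes.

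**Figure D2:**
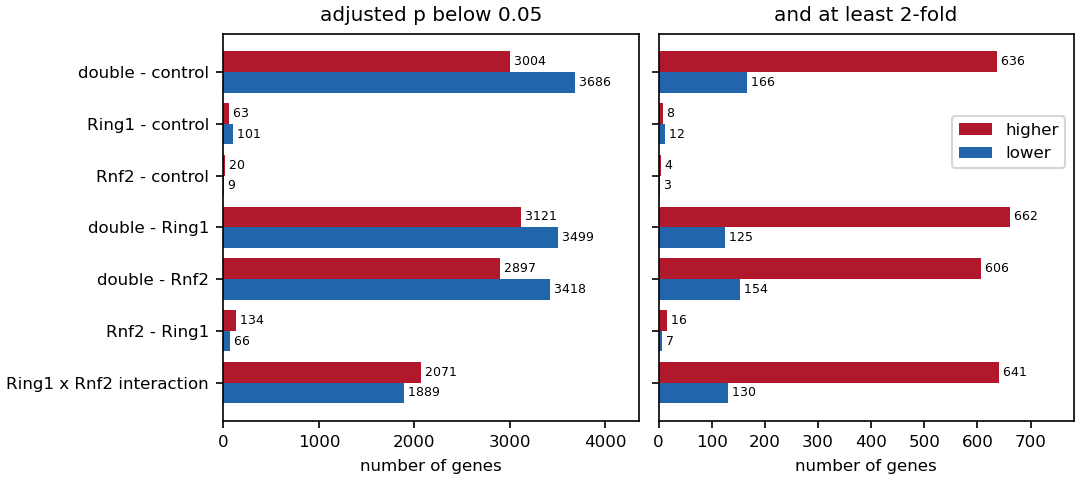
Number of genes called higher (red) and lower (blue) in each comparison by limma at an adjusted p below 0.05 (left) and with at least a 2-fold change as well (right). The double mutant has 3004 genes higher and 3686 lower than control, against 63 and 101 in the Ring1 mutant and 20 and 9 in the Rnf2 mutant.

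Genes that pattern the embryo were prominent among the rises. Of 38 measured Hox genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone). Hoxd8 rose by 3.01 ± 0.11 log2, Hoxd13 by 2.40 ± 0.17 and Hoxd1 by 1.24 ± 0.10. The list stood above other genes in limma's camera (adjusted p = 8.8e-05), a call lost with an estimated correlation (adjusted p = 0.21). Of 165 developmental transcription factors, 46 rose and 7 fell (the same counts adjusted over the list alone), with camera at adjusted p = 1.1e-04 in limma and adjusted p = 0.32 with an estimated correlation. Pax6, needed for eye development, rose by 3.62 ± 0.09, Eomes, a regulator of trophoblast and mesoderm, by 3.56 ± 0.10 and Prrx1, a limb and craniofacial regulator, by 2.47 ± 0.08. A second, dim probe set of Pax6 read -0.06.

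Germline genes were also among the rises, and pluripotency and imprinted genes went both ways. Of 46 germline and meiotic genes that the variant complex PRC1.6 represses in other cells, 19 rose and 6 fell (19 and 8 adjusted over the list alone). Meioc, which keeps germ cells in meiotic prophase, rose by 3.45 ± 0.21 log2, the synaptonemal complex gene Syce1 by 2.60 ± 0.10, and the piRNA pathway genes Mov10l1 by 1.69 ± 0.08 and Mael by 1.19 ± 0.07. Camera in limma gave adjusted p = 6.7e-04 for this list and adjusted p = 0.23 with an estimated correlation. Among 25 pluripotency genes 6 rose and 2 fell, with the same counts adjusted over the list alone. Sox2 rose by 2.46 ± 0.10, Klf4 by 2.06 ± 0.11 and Tbx3 by 0.52 ± 0.08, whereas Sall4 fell by 0.50 ± 0.07. That list did not stand apart in limma's camera (adjusted p = 0.21), with a median of -0.02 and a mean of 0.18. Of 44 imprinted genes 14 rose and 8 fell (14 and 10 adjusted over the list alone), with limma's camera at adjusted p = 0.093. Smoc1 rose by 2.87 ± 0.10, the growth factor gene Igf2 by 2.23 ± 0.11, Ndn by 2.13 ± 0.15 and Sfmbt2 by 2.03 ± 0.10.

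Stress and growth-arrest genes were among the rises. Of 27 p53 target and apoptosis genes 14 rose and 2 fell (14 and 5 adjusted over the list alone), and the list stood above other genes in limma's camera at both the preset (adjusted p = 4.1e-04) and the estimated correlation (adjusted p = 0.047). Plk2 rose by 2.26 ± 0.09 log2, the BH3-only gene Pmaip1 by 2.01 ± 0.16 and Perp by 1.55 ± 0.12. Of 16 cell cycle inhibitors and D cyclins 6 rose and 2 fell (7 and 4 adjusted over the list alone). The growth arrest and DNA damage-inducible genes Gadd45b and Gadd45a rose by 2.103 ± 0.13 and 1.51 ± 0.09, the inhibitor gene Cdkn1c by 1.505 ± 0.10 and Cdkn2a, a classical Polycomb target, by 1.22 ± 0.12. Camera in limma gave adjusted p = 0.043 for this list and adjusted p = 0.32 with an estimated correlation. Of 34 DNA replication licensing genes 1 rose and 15 fell (1 and 16 adjusted over the list alone), including Pole by -0.79 ± 0.09, Orc5 by -0.45 ± 0.07, Gins2 by -0.42 ± 0.06 and Orc3 by -0.41 ± 0.07. That list had an adjusted p of 0.024 in limma's camera, lost with an estimated correlation (adjusted p = 0.32). With centring on the most abundant 25% it had 4 rises and 7 falls, with adjusted p = 0.062 in limma's camera, and the cell cycle list had adjusted p = 0.092 there.

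Transcripts of the oocyte's own programme went both ways. Of 52 oocyte-specific and maternal-effect genes 5 rose and 17 fell (6 and 22 adjusted over the list alone; limma's camera, adjusted p = 0.093). Sohlh1 and Sohlh2, regulators of early oocyte growth, rose by 2.70 ± 0.16 and 2.37 ± 0.13 log2, Basp1 rose by 1.03 ± 0.08 and Nlrp4e fell by 1.19 ± 0.10. Of 42 meiotic cell cycle and spindle genes 4 rose and 11 fell, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.14). The meiotic cohesin gene Smc1b rose by 0.95 ± 0.09, Pde3a, a phosphodiesterase needed for the resumption of meiosis, fell by 0.49 ± 0.06, and Gpr3, a receptor that maintains meiotic arrest, fell by 0.60 ± 0.08. Of 38 genes of maternal mRNA storage and decay 10 rose and 12 fell (11 and 13 adjusted over the list alone; limma's camera, adjusted p = 0.59). There Ddx6 rose by 0.92 ± 0.09 and the decapping enzyme Dcp2 fell by 0.67 ± 0.06. Of 19 genes of zygotic genome activation 2 rose, with the same count adjusted over the list alone (limma's camera, adjusted p = 0.54). These were Pramel17, by 1.72 ± 0.19, and Usp17lc, by 0.66 ± 0.16. The maternal mRNA list had a median of -0.09 and a mean of 0.02, and the zygotic list a median of -0.01 and a mean of 0.09. After quantile normalization the meiotic list had 7 rises and 6 falls and the maternal mRNA list 9 and 6. The oocyte-specific list then had 7 rises and 11 falls, and 8 and 11 when centred on the most abundant 25% of genes.

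Chromatin genes went both ways. Of 32 subunits of Polycomb repressive complex 1, 9 rose and 4 fell, with the same counts adjusted over the list alone. Bcor rose by 2.75 ± 0.10 log2 and Phc3 by 1.17 ± 0.13, and limma's camera gave adjusted p = 0.18 with a median of -0.02 and a mean of 0.15. Of 20 subunits of complex 2 and of the H2A deubiquitinase, 1 rose and 10 fell (2 and 10 adjusted over the list alone; limma's camera, adjusted p = 0.093). Ezhip, an inhibitor of complex 2 that is high in germ cells, fell by 0.65 ± 0.10, Asxl2 by 0.34 ± 0.07 and Eed by 0.34 ± 0.07. Of 43 DNA methylation and histone modifier genes 9 rose and 13 fell (9 and 16 adjusted over the list alone; limma's camera, adjusted p = 0.49), among them the de novo methyltransferase Dnmt3a by -0.52 ± 0.06 and the H3K27 demethylase Kdm6b by -0.61 ± 0.06. Of 17 histone genes 4 rose and 8 fell (4 and 9 adjusted over the list alone; limma's camera, adjusted p = 0.38), with the linker histone H1f2 higher by 1.79 ± 0.10 and Macroh2a1 lower by 0.75 ± 0.08. Of 65 cytosolic ribosomal protein genes 4 rose and 10 fell (2 and 9 adjusted over the list alone; limma's camera, adjusted p = 0.46), and of 66 nuclear oxidative phosphorylation genes 4 rose and 20 fell, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.14). The direction of the last lists turned with the scaling, to 10 rises and 7 falls for ribosomal protein genes and 14 and 9 for oxidative phosphorylation genes when centred on the most abundant 25% of genes. In that scaling the modifier list turned to 12 rises and 11 falls, the complex 1 list had 12 and 1, the complex 2 list 3 and 3, and the histone list 4 and 5.

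Markers of other ovarian cells went both ways. Of 45 granulosa and cumulus cell markers 9 rose and 2 fell, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.21). Ptgs2, a prostaglandin synthase gene, rose by 4.13 ± 0.12 log2, Krt8 by 3.32 ± 0.15 and Gata4 by 1.23 ± 0.08, while the aromatase gene Cyp19a1 fell by 0.78 ± 0.07. Of these 45 markers 26 had a mean above the floor. The granulosa list had a median of -0.03 and a mean of 0.14, and the blood list a median of -0.05 and a mean of 0.08. The steroidogenic genes Cyp11a1 and Star varied widely between arrays of one genotype, Cyp11a1 from 5.28 to 7.34 in control and from 4.07 to 6.501 in the double mutant. Of 22 blood and immune markers 4 rose and 1 fell, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.54), including H2-Aa by 0.99 ± 0.09 and C1qb by 1.05 ± 0.11. Of 20 stromal, theca and endothelial markers 3 rose and 1 fell, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.52), and Myh11 fell by 0.97 ± 0.07. Among 456 genes near Ring1 45 rose and 103 fell (46 and 106 adjusted over the list alone; limma's camera, adjusted p = 0.12), against 62 and 70 when centred on the most abundant 25% of genes. Among 99 genes near Rnf2, which include Ptgs2, 24 rose and 15 fell (25 and 15 adjusted over the list alone; limma's camera, adjusted p = 0.048, and adjusted p = 0.32 with an estimated correlation, a call also lost after quantile normalization with adjusted p = 0.085 and, with 33 rises and 6 falls, when centred on the most abundant 25% of genes with adjusted p = 0.062), with Rgs16 higher by 2.49 ± 0.09 and Glul by 1.73 ± 0.07.

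**Figure D3:**
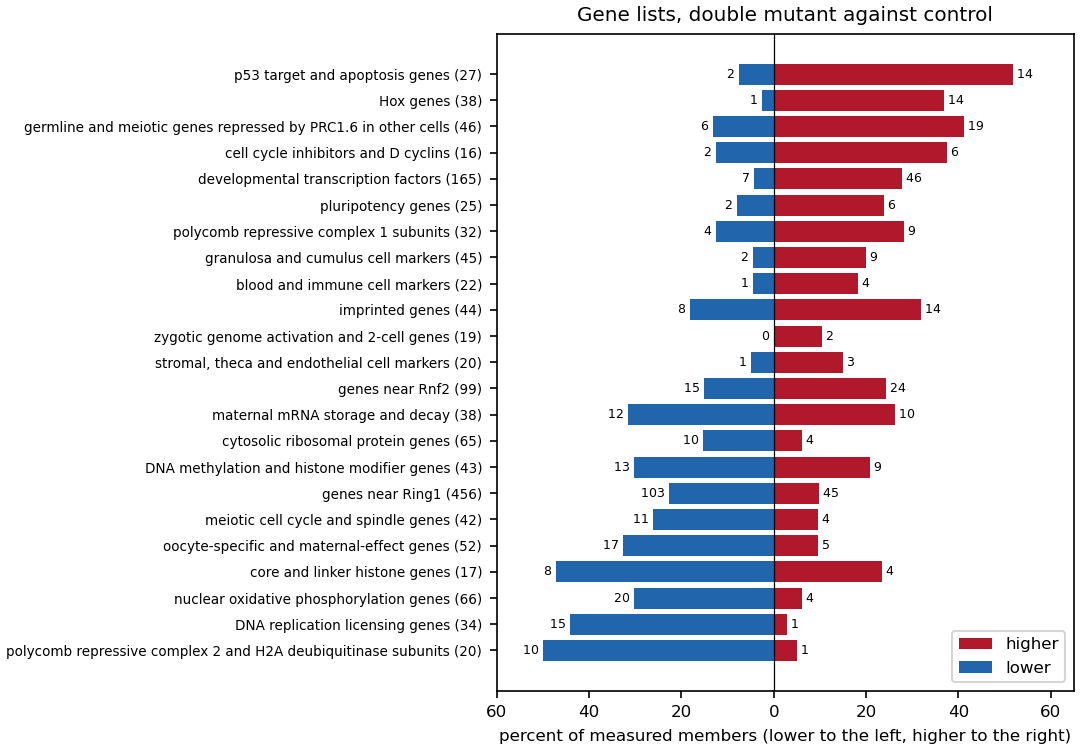
Share of the measured members of each gene list (number measured in brackets) called higher (red, to the right) or lower (blue, to the left) in the double mutant against control; the number at each bar counts genes. In the Hox list 14 of 38 members were higher and 1 lower, and in the replication licensing list 1 of 34 was higher and 15 lower.

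The Ring1 mutant was set against control to ask what loss of this ligase alone does. Gsto2, a glutathione transferase, fell by 4.89 ± 0.23 log2 (limma, adjusted p = 1.5e-06), from 8.38 ± 0.02 in control to 3.49 ± 0.36 (SD, n = 3). Dcpp2 fell by 2.83 ± 0.31, the glycoprotein glucosyltransferase Uggt2 by 2.69 ± 0.25, and Echdc3, Dhtkd1 and Cpn1 changed by -1.65 ± 0.11, -1.51 ± 0.15 and -1.32 ± 0.12. The metal transporter Slc39a8 rose by 2.30 ± 0.30, the prolactin family gene Prl8a2 by 1.19 ± 0.07, the transcription factor Batf3 by 1.17 ± 0.10 and the disulfide isomerase Pdia6 by 1.15 ± 0.12. These 10 genes had limma adjusted p values of at most 0.0046. Several of them stood beside other called genes in chromosome order, so strain-derived DNA in the mixed genetic background is not excluded as a source of their changes. In all, 164 genes were called by limma, 63 higher and 101 lower, and 20 of them changed at least 2-fold. The urea transporter Slc14a1 was called at -2.65 ± 0.55 (limma, adjusted p = 0.0499), but its control arrays had an SD of 1.61 and it read 3.18 in the Rnf2 mutant. Its call was lost without any array but control replicate 3, with adjusted p between 0.0756 and 0.187 in limma.

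No gene list stood apart in the Ring1 mutant by limma's camera. No Hox gene was called. Hoxa7, the brightest of that list, differed by 0.02 ± 0.08 log2. Of 165 developmental transcription factors only Prrx1 was called, lower by 0.50 ± 0.08, and of 25 pluripotency genes only Dppa4, higher by 0.64 ± 0.08. Both had the same counts adjusted over the list alone. The call of Prrx1 was lost without Ring1 mutant replicate 1 (limma, adjusted p = 0.0506), and that of Dppa4 under 1 of the alternatives. A second probe set of Dppa4, with a mean of 5.65 log2, read only 0.14. The maternal genes Gdf9 and Tcl1 differed by -0.01 ± 0.06 and 0.01 ± 0.05. Among 456 genes near Ring1 4 rose and 7 fell (7 and 12 adjusted over the list alone), including Cyp39a1 by -1.05 ± 0.09, Syngr3 by -0.62 ± 0.07 and Pnpla1 by 0.63 ± 0.08. The count of called genes fell when any array of these groups was left out, with fewer arrays to compare. It was 89, 94 and 68 without control replicates 1, 2 and 3, and 71, 82 and 118 without Ring1 mutant replicates 1, 2 and 3. Of these genes 77, 81, 61, 70, 75 and 88, in the same order, were also called with all arrays.

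The Rnf2 mutant was set against control in the same way. Besides Rnf2 itself, Mt1 rose by 4.79 ± 0.17 log2 (limma, adjusted p = 4.2e-08), from 5.39 ± 0.25 to 10.19 ± 0.11 (SD, n = 3). Ptgs2 rose by 1.12 ± 0.12, the placental gene Plac1 by 1.11 ± 0.14, Prl8a2 by 1.04 ± 0.07 and the sulfotransferase Sult2b1 by 0.98 ± 0.09. The fatty acid binding protein Fabp7 rose by 0.78 ± 0.11 and Chrdl1 by 0.74 ± 0.09. Arl8a, a lysosomal GTPase, fell by 1.185 ± 0.11 and the ephrin receptor Epha7 fell by 1.06 ± 0.11. These genes had limma adjusted p values of at most 0.015. The total was 29 genes by limma, 20 higher and 9 lower, of which 7 changed at least 2-fold. The call of Fabp7 is lost without control replicate 3 or Rnf2 mutant replicate 1 or 2, with adjusted p of 0.0524, 0.0836 and 0.10 in limma, and that of Chrdl1 without Rnf2 mutant replicate 2 (limma, adjusted p = 0.0504). Plac1, Ptgs2 and Epha7 each lost their call under 1 of the alternatives.

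No Hox gene or developmental transcription factor was called in the Rnf2 mutant. Hoxa7 differed by -0.00 ± 0.08 and Gbx2 by 0.01 ± 0.09 log2. Of 25 pluripotency genes Dppa4 was called, higher by 0.67 ± 0.08, with the same count adjusted over the list alone. Its call was lost under 2 of the alternatives, and its second probe set read only 0.20. Granulosa and cumulus markers stood above other genes in limma's camera (adjusted p = 7.6e-06) and not with an estimated correlation (adjusted p = 0.50), with Ptgs2 the only one of 45 called (2 higher and 1 lower adjusted over the list alone). Stromal markers (adjusted p = 0.029, and adjusted p = 0.50 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.012, and adjusted p = 0.96 with an estimated correlation) behaved likewise in limma, with no member called in either list or adjusted over the list alone. The count of called genes fell to 16, 16 and 18 without control replicates 1, 2 and 3, to 14 and 10 without Rnf2 mutant replicates 1 and 2, and to 19 without double mutant replicate 3. It was also 16 with the level of Cyp11a1 and Star as a covariate, an alternative chosen after the data were seen.

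**Figure D4:**
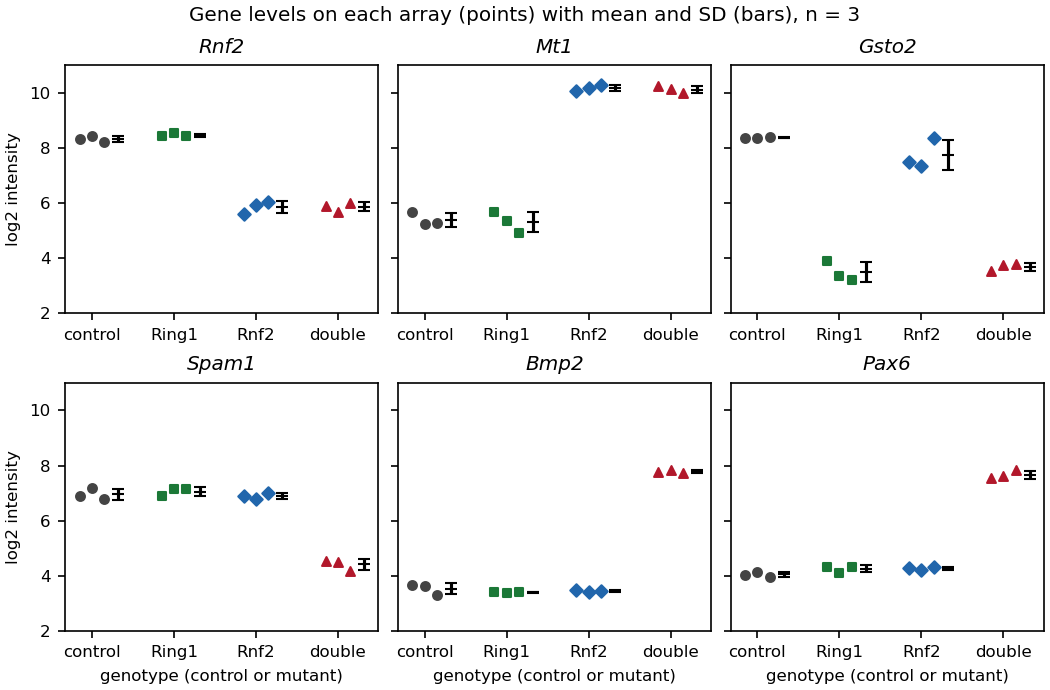
Log2 intensity of 6 genes on each array (points) with the mean and SD per genotype (bars, n = 3). Rnf2 is low and Mt1 high in the Rnf2 and double mutants, Gsto2 is low in the Ring1 and double mutants, and Spam1, Bmp2 and Pax6 differ from control in the double mutant.

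The effect of removing Rnf2 from oocytes that already lacked Ring1 was read from the double mutant against the Ring1 mutant. Against the Ring1 mutant, Plod2 was higher by 4.79 ± 0.11 log2, Tbl1x by 4.62 ± 0.14, Ddah1 by 4.52 ± 0.08, Bmp2 by 4.38 ± 0.09 and the sialic acid acetyltransferase gene Casd1 by 4.17 ± 0.12. Spam1 changed by -2.64 ± 0.12, the tight junction gene Cldn15 by -2.09 ± 0.15, the ammonium transporter Rhbg by -1.84 ± 0.07 and Magea10 by -1.81 ± 0.08. Each had a limma adjusted p of at most 5.8e-07. Hox genes had 13 rises and no fall, and developmental transcription factors 48 rises and 8 falls, with the same counts adjusted over each list alone. The p53 target and apoptosis list had 14 rises and 2 falls (15 and 3 adjusted over the list alone) and kept its camera call with an estimated correlation (limma, adjusted p = 0.032). In total 6620 genes were called by limma, 3121 higher and 3499 lower, and 787 changed at least 2-fold, 662 of them upward. Centred on the most abundant 25% of genes, 3870 were higher and 2457 lower, and centred on the median 2862 and 3879. The balance also turned after quantile normalization, to 3362 and 3248, and without double mutant replicate 2, to 2979 and 2758.

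The effect of removing Ring1 from oocytes that lacked Rnf2 was read from the double mutant against the Rnf2 mutant. Against the Rnf2 mutant, Amigo2 was higher by 4.53 ± 0.13 log2, Ddah1 by 4.41 ± 0.08, Bmp2 by 4.32 ± 0.09, the keratin gene Krt79 by 3.96 ± 0.17 and the GTPase Rhod by 3.84 ± 0.11. Gsto2 changed by -4.05 ± 0.23, Spam1 by -2.48 ± 0.12, the glutathione peroxidase Gpx6 by -2.16 ± 0.09 and Cldn15 by -2.06 ± 0.15. All had limma adjusted p values of at most 7.2e-07. Mt1 differed by -0.07 ± 0.17 (limma, adjusted p = 0.81). Hox genes had 12 rises and no fall, with the same counts adjusted over the list alone, and developmental transcription factors 49 rises and 7 falls (52 and 7 adjusted over the list alone). Granulosa markers had 8 rises and 10 falls (8 and 13 adjusted over the list alone), among them Cyp11a1 by -2.40 ± 0.66 and Star by -1.88 ± 0.52. In limma, Cyp11a1 lost its call without Rnf2 mutant replicates 2 or 3 or double mutant replicates 2 or 3 (adjusted p = 0.0518, 0.0517, 0.0572 and 0.0633). Star lost it without Rnf2 mutant replicate 3 or double mutant replicates 2 or 3 (limma, adjusted p = 0.0671, 0.0604 and 0.0557). In total 6315 genes were called by limma, 2897 higher and 3418 lower, and 760 changed at least 2-fold, 606 upward. Centred on the most abundant 25% of genes, 3969 were higher and 2307 lower, centred on the median 2504 and 4100, and with Cyp11a1 and Star as a covariate 3760 were called, 1963 higher and 1797 lower. The balance also turned after quantile normalization, to 3159 and 3070, and without double mutant replicate 2, to 2789 and 2750.

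The interaction tests whether losing both ligases differs from the sum of the single losses on the log2 scale. Plod2 exceeded that sum by 4.48 ± 0.15 log2, Amigo2 by 4.47 ± 0.18, Bmp2 by 4.45 ± 0.12, Rbm46 by 4.34 ± 0.12 and Ddah1 by 4.29 ± 0.11. Spam1 lay below it by -2.57 ± 0.17, Cldn15 by -2.38 ± 0.22, Gpx6 by -2.08 ± 0.13 and Eps8l3 by -2.01 ± 0.14. The transcription factors Eomes (3.50 ± 0.15), Pax6 (3.18 ± 0.12) and Prrx1 (3.07 ± 0.11), and the stress genes Plk2 (2.22 ± 0.12) and Gadd45a (2.07 ± 0.13), also exceeded it. All had limma adjusted p values of at most 9.8e-06. Altogether 3960 genes were called by limma, 2071 above and 1889 below. Hox genes had 13 positive and no negative calls, with the same counts adjusted over the list alone, and p53 target genes 14 and 0 (15 and 1 adjusted over the list alone). Rnf2 (-0.12 ± 0.16) and Mt1 (0.01 ± 0.24) were not called. Centred on the most abundant 25% of genes, 2500 genes lay above and 1419 below. The balance turned with median centring, to 1853 above and 1980 below, without dim genes, to 1774 and 2214, and with an intensity trend in the variance, to 2247 and 2277.

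The Rnf2-loss effect with Ring1 present and that without Ring1 share no arrays, and their log2 changes correlated across genes at r = 0.178, with 54.5% of genes of one sign. Genes are not independent replicates, and 21 of 100 relabellings of the arrays gave an r at least as high. Relabelling moved the double-mutant arrays between groups, and its r ran from -0.777 to 0.778. An r of 0.178 could not stand out in that range, so these relabellings cannot decide whether the agreement exceeds chance. Of the 29 and 6620 genes called in these Rnf2-loss comparisons, 13 rose in both and 5 fell in both, and 4 went opposite ways. Independent lists would give 2.96 and 1.49 shared rises and falls. The shared calls include Rnf2, the gene removed in both comparisons, and Mt1, which was high in both genotypes with Cre. The Ring1-loss effect with and without Rnf2 correlated at r = 0.116 with 53.2% of one sign. That r was reached by 21 of 100 relabellings, which ran from -0.754 to 0.767 and have the same limit. Between these Ring1-loss comparisons 28 genes rose in both and 54 fell in both, and 31 went opposite ways. Independent lists would give 8.65 and 16.4 shared rises and falls. In both overlaps the spread of each gene came from the same fit of all arrays. A gene with a small spread is thus more readily called in both lists, whatever the direction. No reference was computed that allows for this, and none for calls of opposite direction. These overlaps therefore cannot decide whether the effects agree beyond chance.

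The single mutants were also set directly against each other. Against the Ring1 mutant, the Rnf2 mutant had higher Mt1 (4.87 ± 0.17 log2), Gsto2 (4.25 ± 0.23), Uggt2 (1.95 ± 0.25), Echdc3 (1.599 ± 0.11) and Cpn1 (1.28 ± 0.12), and lower Rnf2 (-2.61 ± 0.11), Batf3 (-1.26 ± 0.10), the ganglioside synthase St8sia1 (-1.05 ± 0.09) and Arl8a (-0.89 ± 0.11). These had limma adjusted p values of at most 0.0038. A total of 200 genes were called by limma, 134 higher and 66 lower in the Rnf2 mutant, of which 23 differed at least 2-fold. Granulosa markers again stood higher in limma's camera (adjusted p = 5.2e-06, and adjusted p = 0.45 with an estimated correlation), with Ptgs2, Krt8 and Nr5a1 called (5 higher adjusted over the list alone). In limma all 3 lost their calls without Ring1 mutant replicate 2 (adjusted p = 0.0705, 0.0705 and 0.124) or Rnf2 mutant replicates 1 (adjusted p = 0.0607, 0.067 and 0.0982) or 2 (adjusted p = 0.0675, 0.0779 and 0.135). Krt8 and Nr5a1 lost them without Ring1 mutant replicate 3 as well (limma, adjusted p = 0.0545 and 0.0514), and Nr5a1 without Ring1 mutant replicate 1 or double mutant replicate 3 (limma, adjusted p = 0.0811 and 0.0519). The total was 82 and 86 without Ring1 mutant replicates 1 and 2, 78 and 65 without Rnf2 mutant replicates 1 and 2, and 42 with Cyp11a1 and Star as a covariate.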

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

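Tests in this part were planned, except those of Mt1, which were chosen after the result was seen. The Ring1 by Rnf2 interaction drew attention because the effect of losing Rnf2 differed between oocytes with and without Ring1, in 3960 genes by limma. The named interaction genes were Plod2 (4.48), Amigo2 (4.47), Bmp2 (4.454), Rbm46 (4.336), Ddah1 (4.29), Rpl27a (-3.073), Spam1 (-2.57), Cldn15 (-2.376), Gpx6 (-2.076) and Eps8l3 (-2.011), all in log2. Rpl27a has other probe sets that read differently. Of 100 relabellings of the 12 arrays into 4 groups of 3, the real one included, 1 gave as many genes, and the highest of the others called 3595. In that set, 2 relabellings kept the 3 double-mutant arrays together as another group, which is where the high count came from, and the 97 that parted them called at most 0. By this share a chance assignment of the arrays is excluded, but the outcome turned on whether the double-mutant arrays stayed together, so it shows that they stand apart and does not test the interaction beyond that.

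Splitting 3 arrays against 3 makes 10 splits, too few for a share under 0.05. The real split was the 1 with the highest count in each pairwise comparison. The double mutant against control called 6690 genes, and the highest other split 0. For the Ring1 mutant the counts were 164 and 0, and for the Rnf2 mutant 29 and 1. For the double mutant against the Ring1 mutant they were 6620 and 0, against the Rnf2 mutant 6315 and 0, and for the Rnf2 mutant against the Ring1 mutant 200 and 1.

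A small share of the probe sets outside the gene-level comparisons also carried signal. These name several genes, no gene or are missing from the annotation. Of 11953 such probe sets, 81 were raised and 102 lowered at least 2-fold in the double mutant against control by limma. Among 21093 genes the counts were 636 and 166, so the upward balance of the genes was not seen over these probe sets as a whole. Those naming several genes did lean upward, with 58 raised and 41 lowered, and those naming no gene leaned downward, with 22 and 59.

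Mt1 stood high in both genotypes that carry the Cre transgene. A response of the metallothionein genes as a class is argued against by the neighbouring Mt2, which changed by 0.089 ± 0.18 log2 in the Rnf2 mutant, and Mt3 read -0.06, although Mt4 rose by 0.41 (limma, adjusted p = 0.034). Candidate explanations that stay open are the transgene itself, since some Cre cassettes carry Mt1 sequence, and the loss of Rnf2. The Mt1 rise differed by 0.0061 ± 0.24 log2 between oocytes with and without Ring1, which either would give. They cannot be told apart here, because every genotype without Rnf2 carries Cre and no group has Cre with intact Rnf2.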

How the results depend on the processing

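The alternative with Cyp11a1 and Star as a covariate and that with centring on the most abundant 25% of genes were chosen after the data were seen; the others were set before the data were examined. Rnf2 kept its direction and call under every alternative but the one without genes near Ring1 and Rnf2, which leaves it out. Counts that moved by over 1.5 times were as follows. A 2-fold threshold left 802 genes for the double mutant against control, 20 for the Ring1 mutant, 7 for the Rnf2 mutant, 787 and 760 for the double mutant against the Ring1 and Rnf2 mutants, 771 for the interaction and 23 for the Rnf2 against the Ring1 mutant, by construction. Fitting only the groups compared, with fewer arrays to estimate the spread, gave 45 genes for the Ring1 mutant, 6 for the Rnf2 mutant and 58 between the single mutants. An intensity trend in the variance gave 289, 51 and 396 in the same order, and leaving out dim genes gave 332 between the single mutants; the cause was not tested. The covariate gave 16 for the Rnf2 mutant, 3760 for the double against the Rnf2 mutant and 42 between the single mutants; the cause was not tested. It turned Star, from which it is built, to 0.0078 in the double against the Rnf2 mutant by construction.

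With the replicate number as a block, the Rnf2 mutant had 18 called genes and the other counts stayed within 1.5 times. The numbers were not taken to pair the samples, since only 4 of 18 same-numbered pairs had a correlation over 0.1 (range -0.159 to 0.207) and 5 of 12 arrays matched their own number best. Replicate 2 of control correlated with that of the Ring1 mutant at 0.109 and of the double mutant at 0.207, and those 2 with each other at 0.134, so something shared by some numbers is not excluded.

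Leaving out each array in turn gave 68 to 168 genes for the Ring1 mutant, 10 to 33 for the Rnf2 mutant and 65 to 197 between the single mutants, with fewer arrays, and 5792 to 6645 for the double mutant against control. Agreement of the Rnf2-loss effects ranged from 0.148 to 0.182 and was 0.227 without dim genes. That of the Ring1-loss effects ranged from 0.0976 to 0.120, and was 0.140 without dim genes and 0.103 after quantile normalization; the cause was not tested. Lists past the threshold in the double mutant against control numbered 7 with the preset correlation, 1 with an estimated one and 19 with fry. These were 7, 1 and 19 against the Ring1 mutant, 9, 1 and 18 against the Rnf2 mutant, 9, 1 and 14 for the interaction, 3, 0 and 0 for the Rnf2 mutant, 0, 0 and 1 for the Ring1 mutant and 1, 0 and 2 between the single mutants; fry puts another question. Of 105 called genes named for the double mutant against control, 102 kept their call under every alternative that held them, against 14 of 29 for the Ring1 mutant and 4 of 18 for the Rnf2 mutant. No other named gene changed sign where called. With probe sets kept apart, a gene was read from its probe set closest to the main value. That alternative therefore could not lose or reverse a gene through its other probe sets, such as those of Rpl27a, which differed in direction. Centring on the most abundant 25% moved the median of all genes by 0.0975 log2, and 2408 of the 3686 falls in the double mutant against control stayed called. Genes near the floor have compressed changes. Simulated changes of 0.3 log2 were recovered in 20% of cases, with far fewer genes changed than in the real double mutant.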

Other observations

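The tests in this part were chosen after the results were seen. The prediction for the test with 1 gene per family was written beforehand, although the excess on X that it weighs was noticed in these data. X-linked genes were frequent among the transcripts raised at least 2-fold in the double mutant. Of 742 measured genes on X, 58 rose at least 2-fold, or 7.82%, against 3.04% of autosomal genes. Beyond Tbl1x and Xlr, they included the growth factor gene Fgf16 (3.72 ± 0.12 log2), Plac1 (3.78 ± 0.14), the nucleotide synthesis gene Prps2 (3.65 ± 0.18), the scaffold gene Cnksr2 (3.52 ± 0.08), Chrdl1 (3.32 ± 0.09) and Mageb4 (3.203 ± 0.12), chosen after their values were seen, each with a limma adjusted p of at most 1.95e-08. In the Rnf2 mutant Plac1 (1.11) and Chrdl1 (0.74) rose as well, while Tbl1x (0.40), Xlr (0.30), Prps2 (0.25), Cnksr2 (0.16), Fgf16 (0.11) and Mageb4 (0.03) were not called there. In the Ring1 mutant none of these 8 genes was called by limma, with values from -0.08 for Tbl1x to 0.26 for Chrdl1.

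The odds ratio of a 2-fold rise on X was 2.71 (Fisher's exact test, two-sided, adjusted p = 8.8e-09 over 20 chromosomes), and X was the only one of them past the threshold. This describes the excess in the counts where it was noticed and is no independent test of it. Counting a few gene families many times does not account for it, since with 1 gene kept per symbol stem and chromosome the odds ratio was 2.98 (95% interval 2.104 to 4.13). The excess held for genes below the olfactory 95th percentile in control (8.25% on X, 2.35% on autosomes) and above it (7.34% and 3.50%). Its cause was not tested.

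Genes called in the Ring1 mutant lay near one another in the genome, and a candidate explanation for those near Ring1 is strain-derived DNA in the mixed genetic background. Within 10 Mb of Ring1, 2.41% of genes were called, against 0.741% averaged over all other genes (odds ratio 3.31, 95% interval 1.61 to 6.15, Fisher's exact test, two-sided, p = 9.1e-04). Calls also gathered elsewhere, as on chromosomes 12 and 19, so this does not show that they concentrate at Ring1. A segment carried along with the Ring1 null allele would give an excess there. Such a segment would also set the double mutant apart from the Rnf2 mutant, where 6 of the 11 genes were called in the same direction by limma, against 76 of 153 elsewhere, while Atp6v0e (0.14), Ccnf (0.08), Pnpla1 (0.11) and Trim39 (0.08) were not called and H2-K1 turned from -0.48 to 1.06, so this recurrence says nothing particular about the region. Outside that region, 81 of 145 called genes had another called gene 0.5 to 5 Mb away, against a median of 67 in 10000 random gene sets (permutation p = 0.038), and in the Rnf2 mutant 7 of 25 did, against a median of 2 (permutation p = 0.043), which describes the grouping where it was noticed and tests no cause of it. In chromosome order, Gsto2 and Cpn1 stood among other genes called on chromosome 19, and Dhtkd1 and Echdc3 among those on chromosome 2. Pdia6 did so on chromosome 12, and Dcpp2 stood beside the calls near Ring1 on chromosome 17. Effects of Ring1 loss and of strain-derived DNA cannot be told apart for these genes here. That includes Gsto2 in the double mutant against the Rnf2 mutant. Direct effects of Ring1 loss on neighbouring genes stay open and untested.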
